A study of Caenorhabditis elegans with 18 samples.

How the data were processed

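Small RNAs were sequenced from whole Caenorhabditis elegans animals at the last larval stage (L4), grown at 15 °C. The 3 strains carried a FLAG tag on the Argonaute WAGO-1, on WAGO-1 in animals with a deletion in dpf-3, or on the Argonaute WAGO-3. From each strain, per the labels' protocols, RNA bound to the tagged protein was recovered with anti-FLAG beads (the immunoprecipitate, IP) and total RNA was taken from the same kind of extract (the input). There were 18 libraries in 6 groups of 3. Per the labels, a small RNA enrichment step was applied to the inputs and left out for the IPs, and the RNA was treated with a 5' polyphosphatase, which lets RNAs with a 5' triphosphate enter a library. Libraries were then made with a kit for microRNAs. Such libraries hold mainly short RNAs, many of them antisense to the gene they are counted under, so a count here is not a level of messenger RNA.

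The deposited table held read counts, not normalised, for 18 columns, all of which matched a library title. The submitters' processing notes name cutadapt 2.3, Bowtie 1.2.3, SAMtools 1.9 and HTSeq 0.11.2 and the genome build ce11. The annotation, the strand setting, the treatment of reads with several positions and any use of molecular identifiers are not given in the sources used here. Sense and antisense reads therefore cannot be told apart, nor reads of overlapping genes, and values of gene families with near-identical copies (histones, collagens, major sperm proteins, ribosomal proteins and the neighbouring F55C9 genes) are uncertain. The table had 20134 genes, 55259 genomic intervals that carry a position and strand but no name (median of end minus start 139 bases) and 5 summary lines, of which 3 were 0 throughout. It had no line for a microRNA, piRNA, transfer RNA or ribosomal RNA gene. Of the genes, 19579 matched the RefSeq table of assembly WBcel235, the same assembly as ce11, and 19832 had a symbol or sequence name. The reads assigned to no feature made up 68.6% to 82.4% of all counted reads in the inputs and 32.5% to 38.6% in the IPs, and they stayed out of library sizes and tests. Reads assigned to several features made up at most 0.176%.

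Counts in genes and intervals totalled 2206087 to 5649896 per IP and 88761 to 517278 per input, so changes of weakly covered features are far less precise in the inputs than in the IPs. A count of 3 was used as the floor that a count of 0 allows, and 3 counts over the 3 libraries of a group corresponded to 0.183 to 4.10 counts scaled to 1e+06 per library (CPM). Where all 3 libraries of a group were at 0, a fold is given against that floor as a lower bound. Where a group held 1 to 3 counts, the ratio is given with an exact 95% interval. Floors and intervals cover counting error only, because it is not stated whether molecules were counted once.

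edgeR 4.0.16 (R 4.3.3) was used with filterByExpr at a minimum count of 10, which kept 11648 of 75393 features (9869 genes and 1779 intervals). One quasi-likelihood model with a mean per group was fitted to the 18 libraries with TMM factors, and 7 contrasts were tested with glmQLFTest. The design, gene lists, rule for named genes and most alternatives were fixed before the data were examined. A feature was called at a Benjamini-Hochberg adjusted p under 0.05, and a feature at least 2-fold higher in an IP was called enriched. Standard errors (SE) of log2 folds are the absolute log2 fold divided by the square root of the F statistic. Levels are CPM of the TMM-scaled library, as mean ± SD with n = 3 in every group. The genes named are the 10 largest log2 folds per direction among called features with at least 20 CPM in a group and no overlap between the groups compared, up to 4 members of each list with the smallest p, and the targeted genes. Only part of those the rule gives are printed.

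TMM factors ranged from 0.431 to 2.39, and the scaling sets where 0 lies in every contrast. With total counts per library as the scaling, the median log2 fold over all features shifted by -1.44, -1.07 and -1.63 in the IPs against inputs of WAGO-1, WAGO-1 in the dpf-3 deletion and WAGO-3. It shifted by 1.12 between the WAGO-1 IPs, 0.77 between their inputs, 0.37 in the change of enrichment, and -0.18 between the enrichments with the 2 proteins. The TMM scale also depends on the library edgeR takes as its reference, here replicate B of the deletion IP. Folds are given relative to the TMM scale, with the split of calls under total counts beside each main split.

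Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Their p-values were adjusted over lists and the 7 comparisons, and within the comparison for 1 added later, and members were also counted with p-values adjusted over the list alone. The lists were written from general knowledge of the field. Of the 24 loci listed as known targets of mutator-dependent 22G RNAs, 17 had counts in the table and 16 were tested, and microRNA and piRNA genes could not be tested as lists. The count filter kept 27 of 161 collagen, 6 of 16 muscle, 8 of 18 neuron and 7 of 17 intestine genes. Results of these lists cover only the better covered members. Shares of counts were compared with exact two-sided permutation tests, whose smallest p is 0.1 with 3 libraries against 3. The alternatives were DESeq2 1.42.0, other scalings, filters and sets of libraries, the replicate letter as a block, and each library left out in turn. Scaling by microRNAs could not be run.

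Replicates carry the letters A, B and C. No pair of libraries was identical, and counts of most replicate pairs differed by little more than sampling noise, with a chi-square per degree of freedom of 1.05 to 1.54. The exceptions were the A libraries of both WAGO-1 IP groups, at 5.23 and 7.44 against B and C in animals with intact dpf-3 and 3.55 and 2.46 in the deletion. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Deviations of same-letter libraries from their group means correlated above 0.1 at every letter only between the WAGO-1 IPs of both genotypes (0.419, 0.179 and 0.134). Libraries of unlike letters reached 0.362 there, above the values at B and C. A pairing by letter is therefore not shown beyond the A libraries, and the main fit uses none.

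The procedure was tested on simulated counts with 100 features changed 2-fold and 100 changed 4-fold, drawn only from the better covered of the 11648. It recovered 86% and 100% of them between the WAGO-1 IPs, 55% and 93% between WAGO-1 IP and input, 17% and 61% between the inputs, and 17% and 54% for the change of enrichment. False calls made up 4.62%, 5.73%, 11.4% and 11.2% of the calls in the same order. Apart from these changes, the groups compared were simulated with the same composition, and all features with the same dispersion. The rates therefore do not cover weakly covered features, the shifts between scalings or the outlying A libraries.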

Results

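The data are counts of small RNAs over genes and unnamed intervals in 6 groups of 3 libraries: IPs of FLAG-tagged WAGO-1, of WAGO-1 in animals with a dpf-3 deletion and of WAGO-3, and the input of each strain. WAGO-1 and WAGO-3 are Argonautes that carry 22G RNAs, short secondary small RNAs antisense to silenced transcripts, and dpf-3 encodes a dipeptidyl peptidase. The title of the series names proteolytic processing of Argonautes as the subject. The comparisons ask which small RNAs each protein holds and how that content differs when dpf-3 is deleted. IP libraries had 2.21e+06 to 5.65e+06 counts in features and inputs 88761 to 517278.

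Small RNAs from the targeted genes themselves come first. Reads from dpf-3 (chromosome I, 6838354 to 6843343, build ce11) stood at 39 ± 11.7 per 1e+06 feature counts in the WAGO-1 input (SD, n = 3), 51 ± 19 in the WAGO-3 input and 18.9 ± 9.46 in the input of the dpf-3 deletion. The log2 fold between the WAGO-1 inputs was -1.72 ± 0.59 (SE, edgeR adjusted p = 0.0199), and with total counts per library it was -0.96, where the call was lost (adjusted p = 0.217). It was also lost without replicate A of the WAGO-1 input (-1.57) or replicate C of the deletion input (-1.34). In the IPs, dpf-3 was not called between the genotypes and its direction rests on the scaling, with log2 folds of -0.54 ± 0.36 (edgeR adjusted p = 0.186) and 0.58 with total counts (adjusted p = 0.116). The deletion input held 6 reads from dpf-3 and the deletion IP 51, and since small RNAs are not messenger RNA, this is a weak check of the genotype. Reads from wago-1 stood at 62.2 ± 37.7 in the WAGO-1 input, 139 ± 39.2 in the WAGO-3 input and 340 ± 74.1 in that of the deletion. Those from ppw-2, which encodes WAGO-3, stood at 263 ± 48.0, 287 ± 21.1 and 1303 ± 107 in the inputs of WAGO-1, WAGO-3 and the deletion.

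Unnamed intervals took very different shares of the counts in the 6 groups. They made up 31.2% ± 0.018 of feature counts in the WAGO-1 IP and 26.5% ± 0.206 in its input (SD, n = 3), against 12% ± 0.056 and 8.32% ± 0.057 in the IP and input of the dpf-3 deletion. In the WAGO-3 IP and input they made up 23% ± 0.089 and 14.2% ± 0.162. The 22G-silenced loci took 3.60% of feature counts in the WAGO-1 IP and 2.09% in that of the deletion, and 6.25% and 5.24% in the inputs. Cytosolic ribosomal protein genes took 0.0384% in the WAGO-1 IP and 0.276% in that of the deletion. In each of these pairs the 3 libraries of one group lay outside the range of the other. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give.

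**Figure D1:**
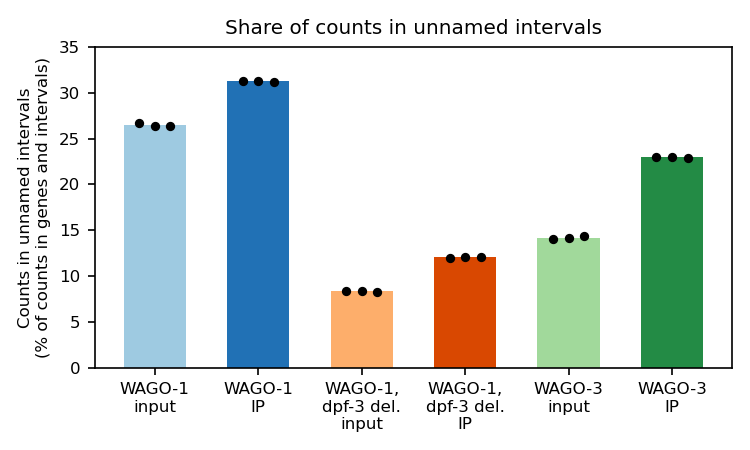
Percent of the counts in genes and intervals that fell in unnamed intervals, for each of the 6 groups; bars are means and points the 3 libraries. The share was 31.2% in the WAGO-1 IP and 12% in that of the dpf-3 deletion, and the libraries of a group lay within 0.5 percentage points of one another.

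The comparison of the WAGO-1 IP with its input shows which small RNAs took a larger or smaller part of the IP. The samples hold no IP from an untagged strain, and the small RNA enrichment step was applied to the inputs alone. Binding to the tagged protein therefore cannot be told apart from bead background or from this difference in preparation. The same holds for the other IPs set against their inputs. Small RNAs from his-24, a linker histone gene, stood at 16460 ± 2120 CPM in the IP and 2602 ± 73.5 in the input (log2 fold 2.66 ± 0.075 SE, adjusted p = 1.25e-65), and those from unc-54, a muscle myosin heavy chain, at 514 ± 22.5 and 85.7 ± 17 (2.52 ± 0.13). The collagen gene col-71 (2.28 ± 0.10) and prg-1, the Argonaute that binds piRNAs (1.69 ± 0.08), were also higher in the IP, though for prg-1 the log2 fold was 0.23 with total counts. Small RNAs from T21B6.3 rose from 3.27 ± 3.2 to 55.6 ± 9.89 CPM. Those from rab-3, a GTPase of synaptic vesicles, had 209 reads in the IPs and 2 in the inputs, a ratio of 22.7 (exact 95% interval 6.22 to 189), and those from abu-6 and C44C1.1 had ratios of 30 (5.3 to 1190) and 26.9 (7.36 to 223).

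Other loci were nearly absent from the WAGO-1 IP. Small RNAs from the neighbouring genes F55C9.5 and F55C9.3 (chromosome V, 19290616 to 19293125 and 19287009 to 19288173) fell by 6.52 ± 0.17 and 6.35 ± 0.12 on the log2 scale, from 488 ± 33.8 to 5.17 ± 0.71 CPM and from 1796 ± 230 to 22.2 ± 5.77. Log2 folds were -6.29 ± 0.15 for the F-box gene fbxa-52, -6.22 ± 0.15 for pals-26 and -6.16 ± 0.25 for Y43F8B.17. Y47H10A.5 and K02E2.6, both from the list of 22G-silenced loci, fell by 4.17 ± 0.08 and 3.45 ± 0.08. An unnamed interval at chromosome IV, 12925373 to 12925435, minus strand, had 232 reads in the inputs and 1 in the IPs, a ratio of 1070 (exact 95% interval 189 to 42300), and no RefSeq gene overlaps it.

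By list, 48 of 69 spermatogenesis genes were lower in the WAGO-1 IP and 5 higher (camera adjusted p = 8.37e-08, and adjusted p = 0.0491 with an estimated correlation). Among them spe-12 fell by 5.86 ± 0.25 and ssp-16 by 3.15 ± 0.17. Of 40 small RNA pathway genes 25 were lower and 7 higher (adjusted p = 1.53e-04, and 0.0323 with an estimated correlation), among them csr-1, an Argonaute of the germ line, which fell by 2.65 ± 0.14. Of 30 germline genes 19 were lower and 4 higher (adjusted p = 1.35e-04, and 0.0491 with an estimated correlation), and pgl-1, a component of germ granules, fell by 1.56 ± 0.15. The 22G-silenced loci split into 10 lower and 6 higher of 16 (adjusted p = 2.02e-06, and 0.0781 with an estimated correlation). Of the 27 collagen genes that passed the filter, from 161 counted, 22 were higher and 3 lower (adjusted p = 0.0011, and 0.266 with an estimated correlation). Of 71 ribosomal protein genes 28 were lower and 7 higher (adjusted p = 0.0034, and 0.489 with an estimated correlation). Members adjusted over the list alone gave counts of higher and lower of 5 and 48, 7 and 25, 4 and 19, 6 and 10, 22 and 3, and 6 and 27, in the order of these lists. Histone genes (16 higher and 12 lower of 69), muscle genes (4 and 0 of 6), neuron genes (6 and 0 of 8) and intestine genes (1 and 1 of 7) did not pass camera, which sets a list against all other features, with adjusted p of 0.31, 0.528, 0.536 and 0.607. In fry, which asks whether the members themselves move from 0 on the TMM scale, muscle and neuron genes were up (adjusted p = 1.76e-08 and 3.06e-06).

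Over all features, 5037 were higher and 2895 lower in the WAGO-1 IP in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With total counts per library as the scaling the split was 1425 higher and 5696 lower, so the number of features called higher rests on the scaling. On that scale 11 collagen genes were higher and 3 lower, 60 spermatogenesis genes were lower and none higher, and histone genes split into 2 higher and 54 lower. Higher and lower counts there were 2 and 34 for small RNA pathway, 1 and 26 for germline, 3 and 13 for 22G-silenced, 0 and 59 for ribosomal, 1 and 1 for muscle and for neuron, and 0 and 1 for intestine genes. The ribosomal list lost its call on that scale (adjusted p = 0.0739).

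In the dpf-3 deletion, the same comparison was made between the WAGO-1 IP and its input. The gene his-24 was again higher in the IP (3455 ± 262 against 601 ± 72.3 CPM, log2 fold 2.52 ± 0.09, adjusted p = 4.54e-54), as were unc-54 (2.73 ± 0.19), col-71 (2.37 ± 0.29), unc-104, a kinesin of axonal transport (2.38 ± 0.36), and prg-1 (1.28 ± 0.09, and 0.20 with total counts). Small RNAs from frpr-14, a predicted neuropeptide receptor, stood at 42.7 ± 3.73 CPM in the IP and had no read in the 3 inputs, which makes them at least 10.4-fold higher. For sto-4, a stomatin, the bound was at least 6.71-fold. At the low end, log2 folds were -6.92 ± 0.14 for pals-26 (6593 ± 1030 to 54 ± 12.5 CPM), -6.81 ± 0.19 for F55C9.5, -6.53 ± 0.12 for F55C9.3, -6.54 ± 0.18 for spe-12, -7.28 ± 0.53 for T25F10.1 and -6.84 ± 0.42 for F44E2.4. Y47H10A.5 fell by 3.96 ± 0.08, and klp-7, a microtubule-depolymerising kinesin active in germ cells, by 1.15 ± 0.11.

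Spermatogenesis genes were lower for 38 of 69 and higher for 2 (adjusted p = 1.11e-06, and 0.024 with an estimated correlation), and 22G-silenced loci were lower for 9 and higher for 4 of 16 (adjusted p = 3.87e-13, and 0.0141 with an estimated correlation). Germline genes were lower for 16 and higher for 4 of 30 (adjusted p = 0.0048, and 0.0868 with an estimated correlation). Adjusted over the list alone, the higher and lower counts of these lists were 2 and 38, 4 and 9, and 4 and 17. The other lists did not pass camera: small RNA pathway genes (8 higher and 16 lower of 40, adjusted p = 0.0633), ribosomal protein genes (19 and 3 of 71, 0.69), collagen genes (13 and 3 of 27, 0.528), histone genes (14 and 1 of 69, 0.713), muscle genes (3 and 0 of 6, 0.259), neuron genes (6 and 0 of 8, 0.259) and intestine genes (0 and 0 of 7, 0.643). Of these, fry called small RNA pathway genes down (adjusted p = 2.33e-04) and muscle (2.40e-06), neuron (4.18e-05), collagen (0.0083) and histone genes (0.0285) up. In all 3829 features were higher and 2465 lower by edgeR's test. The split was 1487 and 4320 with total counts and 5769 and 1264 with all counted reads as the scaling, so it rests on the scaling. With total counts, small RNA pathway genes split into 1 higher and 28 lower and passed as a list (adjusted p = 1.25e-06), ribosomal protein genes into 3 and 26, histone genes into 3 and 13, and collagen genes into 5 and 3. The other splits were 1 and 56 for spermatogenesis, 3 and 12 for 22G-silenced, 1 and 24 for germline, 1 and 0 for muscle, 2 and 0 for neuron and 0 and 1 for intestine genes.

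With WAGO-3, small RNAs from his-24 were again higher in the IP than in the input (28420 ± 1150 and 3513 ± 391 CPM, log2 fold 3.01 ± 0.08, adjusted p = 2.55e-71). The collagen genes col-157 (1957 ± 120 against 158 ± 27.2 CPM, 3.62 ± 0.11) and col-139 (4.14 ± 0.20), prg-1 (5075 ± 255 against 718 ± 49.0, 2.82 ± 0.09) and the sperm gene spe-41 (2.25 ± 0.14) were higher in the IP. An unnamed interval at chromosome III, 7470316 to 7470387, minus strand, was at least 13-fold higher in the IP, at 39.2 ± 1.15 CPM. The intestinal genes vit-6, a yolk protein, and vha-6, a proton pump subunit of the gut, were lower, with 11 reads in the input and 1 in the IP for vit-6 (ratio 45.5, exact 95% interval 6.62 to 1960) and a fall of 3.09 ± 0.64 for vha-6. F38H4.6 and mps-3, a potassium channel subunit, were at least 46.3-fold and 29.2-fold lower in the IP, where neither had a read.

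All 7 intestine genes tested were lower with WAGO-3 (adjusted p = 0.0412, and 0.126 with an estimated correlation or 0.13 with total counts). Spermatogenesis genes were lower for 59 of 69 and higher for 3 (adjusted p = 2.28e-09, and 0.0173 with an estimated correlation), with spe-12 falling by 4.34 ± 0.18, ssp-16 by 4.24 ± 0.25, and spe-10 at 27 reads in the input and 1 in the IP (ratio 112, exact 95% interval 18.4 to 4580). The ratio of F55H12.3 was 114 (30.1 to 964). Of the 22G-silenced loci 9 were lower and 6 higher of 16 (adjusted p = 2.34e-05, and 0.0825 with an estimated correlation), with Y47H10A.5 falling by 5.48 ± 0.09 and K02E2.6 by 4.74 ± 0.09. The interval on chromosome IV at 12925373 was nearly absent from this IP too, at 305 reads in the input and 2 in the IP (ratio 631, exact 95% interval 173 to 5240). Of 27 collagen genes 17 were higher and 3 lower (adjusted p = 3.83e-04, and 0.128 with an estimated correlation). Adjusted over the list alone, the higher and lower counts were 0 and 7, 3 and 60, 6 and 9, and 17 and 4. Germline genes (6 higher and 9 lower of 30, adjusted p = 0.352), small RNA pathway genes (12 and 16 of 40, 0.652), histone genes (19 and 5 of 69, 0.889), ribosomal protein genes (8 and 19 of 71, 0.0617), muscle genes (2 and 0 of 6, 0.781) and neuron genes (3 and 1 of 8, 0.972) did not pass camera. Of these, fry called small RNA pathway (adjusted p = 0.0022), histone (0.0044), muscle (1.20e-04) and neuron genes (0.0277) up. For small RNA pathway genes that direction goes against their median log2 fold (-0.29) and their larger number of lower members, so no direction is drawn for them. With total counts germline genes (0 higher and 26 lower, adjusted p = 8.61e-04) and small RNA pathway genes (2 and 33, 7.31e-04) passed, histone genes split into 2 and 31, and collagen genes into 10 and 6. The other splits were 0 and 49 for ribosomal, 2 and 63 for spermatogenesis, 4 and 11 for 22G-silenced, 0 and 7 for intestine, and 0 and 1 for muscle and for neuron genes. Of all features, 4051 were higher and 3120 lower by edgeR's test, and 1177 and 6085 with total counts.

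The enriched features of the 3 IPs overlapped. At 2-fold or more, 4451 features were enriched with WAGO-1, 3544 with WAGO-1 in the dpf-3 deletion and 3687 with WAGO-3. WAGO-1 shared 3077 with WAGO-1 in the deletion, where independent lists would share 1354, and 2626 with WAGO-3, where independent lists would share 1409. The deletion and WAGO-3 shared 2149 against 1122. These comparisons have no library in common, but all share the difference in preparation between IPs and inputs. Intervals were also called higher more often than genes in each (77%, 46.9% and 72.5%, against 37.2%, 30.3% and 28%). Independent lists are therefore a low baseline, and the excess does not by itself show shared targets. With total counts the shared numbers were 291, 68 and 111, against 54.5, 32.0 and 59.4 for independent lists.

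The WAGO-1 IP of the dpf-3 deletion was set against the WAGO-1 IP with dpf-3 intact, to see how the content of WAGO-1 differs with the genotype. Small RNAs from ifg-1, a translation initiation factor, rose from 16.7 ± 2.39 to 867 ± 31.9 CPM (log2 fold 5.73 ± 0.12, adjusted p = 1.02e-81), and those from larp-1, an RNA-binding protein of the germ line, from 18.9 ± 0.52 to 601 ± 20.0 (4.98 ± 0.11). The splicing factor gene prp-8 (4.66 ± 0.11), the pseudouridine synthase gene dkc-1 (4.41 ± 0.19) and ppw-2, the gene of WAGO-3 (59.1 ± 0.76 to 1308 ± 3.46 CPM, 4.46 ± 0.09), rose too. In the opposite direction, small RNAs from the 22G-silenced locus C38D9.2 fell by 5.52 ± 0.08, from 9548 ± 554 to 208 ± 5.05 CPM, and those from F15D4.5 by 3.44 ± 0.07, from 30730 ± 2910 to 2841 ± 157. An interval at chromosome III, 3446009 to 3446159, minus strand, had no read in the deletion IPs and was at least 201-fold lower. Intervals at chromosome III, 6630737 to 6631713 (fell by 8.19 ± 0.15, from 394 ± 12.5 to 1.32 ± 0.56 CPM), and X, 16234996 to 16236011, over F23A7.5 (fell by 7.85 ± 0.16) were also nearly lost, as was the gene K08D12.4 (fell by 6.98 ± 0.19).

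**Figure D2:**
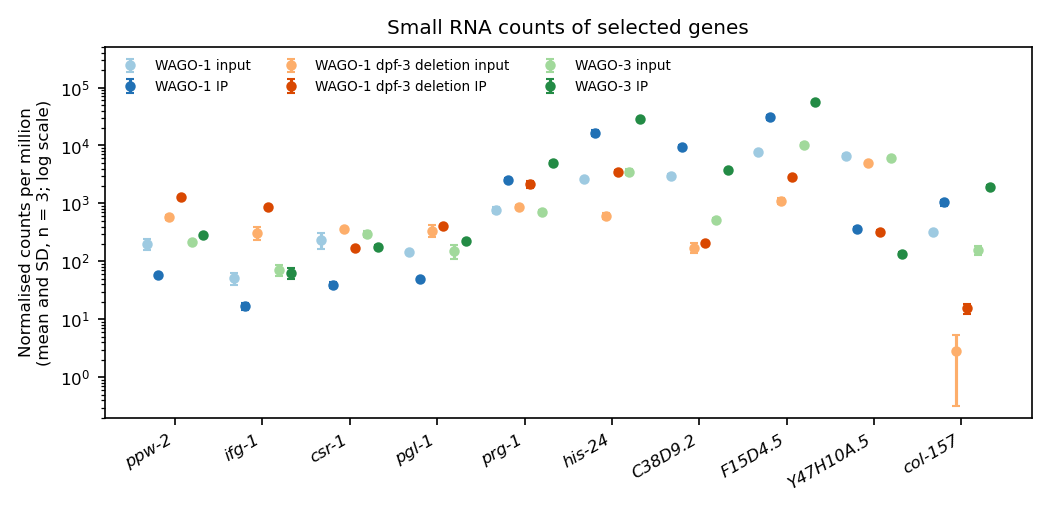
Normalised CPM of small RNAs from 10 genes in the 6 groups, on a log scale; points are means and bars the SD over 3 libraries. Small RNAs from C38D9.2 stood at 9548 in the WAGO-1 IP and 208 in that of the dpf-3 deletion, and those from ppw-2 at 59.1 and 1308.

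Ribosomal protein genes moved together between the WAGO-1 IPs: 65 of 71 were higher in the deletion and none lower (camera adjusted p = 2.36e-15, and adjusted p = 0.0935 with an estimated correlation). Among them rps-25 rose by 5.17 ± 0.23 and rpl-39 by 4.34 ± 0.18. Small RNA pathway genes were higher for 24 of 40 and lower for 4 (adjusted p = 2.89e-06, and 0.013 with an estimated correlation), including wago-1 (2.67 ± 0.18), mut-16, a scaffold of mutator foci (2.45 ± 0.12), and csr-1 (2.06 ± 0.11). Germline genes were higher for 21 of 30 and lower for 5 (adjusted p = 1.35e-04, and 0.0491 with an estimated correlation), including pgl-1 (3.03 ± 0.10) and daz-1, an RNA-binding protein of oogenesis (2.95 ± 0.16). Collagen genes were lower for 20 of 27 and higher for 1 (adjusted p = 5.87e-07, and 0.0173 with an estimated correlation). Of these, col-154 changed by -6.06 ± 0.13, col-157 by -6.04 ± 0.10 and col-111 by -5.57 ± 0.09, and the direction of the list's median was kept with total counts (-2.75 and -1.62), where 8 were higher and 17 lower. There ribosomal protein genes were higher for 71, small RNA pathway genes for 37 and germline genes for 29, with none lower.

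Of the 22G-silenced loci, 14 of 16 were lower and 1 higher (adjusted p = 3.74e-05, and 0.0888 with an estimated correlation), with log2 folds of -4.85 ± 0.09 for C18D4.6 and -4.23 ± 0.09 for R06C1.4. The median of this list changed sign with total counts (-0.81 and 0.33), where 5 were lower and 7 higher. R06C1.4 also differed between the WAGO-3 and WAGO-1 inputs, both with dpf-3 intact, by -4.20 ± 0.16. Adjusted over the list alone, the higher and lower counts were 65 and 0, 25 and 4, 22 and 5, 1 and 21, and 1 and 15 for ribosomal, small RNA pathway, germline, collagen and 22G-silenced genes. Histone genes (9 higher and 37 lower of 69, adjusted p = 0.259) did not pass as a list, and with total counts 45 were higher and 15 lower. The histone genes his-61 and his-24 fell by 5.24 ± 0.14 and 2.25 ± 0.07, and his-61 was also lower in the WAGO-3 than in the WAGO-1 input, by 4.75 ± 0.32. Spermatogenesis genes (12 and 5 of 69, 0.259, and 50 and 2 with total counts) did not pass either, and spe-41 fell by 2.53 ± 0.10. Neuron genes (5 and 1 of 8, 0.303), muscle genes (2 and 3 of 6, 0.959) and intestine genes (0 and 1 of 7, 0.713) did not pass, and with total counts they split into 7 and 0, 4 and 0, and 5 and 0. Of the lists that did not pass camera, fry called histone (adjusted p = 3.95e-07) and muscle genes (0.005) down and neuron genes up (6.42e-04).

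In all, 3559 features were higher and 3709 lower in the WAGO-1 IP of the deletion by edgeR's test: 3502 and 2226 genes, and 57 and 1483 intervals. With total counts the split was 8081 and 1964. The 2 scalings differ by 1.12 in the median. Without replicate A, B or C of the WAGO-1 IP 5745, 5397 and 5456 features were higher, because edgeR then took another library as the TMM reference. With the reference kept the counts were 3451, 3141 and 3132. Intervals lay below genes by 2.12 at the median. Features enriched with WAGO-3, a set from libraries outside this contrast, were lower for 2363 and higher for 687 of 3687, and other features lower for 1346 and higher for 2872 of 7961. With total counts the WAGO-3-enriched features were lower for 1614 and higher for 1632 (median 0.025) and other features lower for 350 and higher for 6449 (median 1.42). Of the lower calls with WAGO-3-enriched features, 1189 were intervals. The 2407 genes among them split into 659 higher and 1174 lower (median -0.278), and with total counts into 1513 higher and 665 lower (median 0.858), so their direction rests on the scaling. Between the inputs the WAGO-3-enriched features were also lower, for 1428 against 154 higher (median -1.19, and -1.12 between the IPs). With total counts 1078 were lower there and 554 higher. Their fall is therefore not particular to the WAGO-1 IP.

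**Figure D3:**
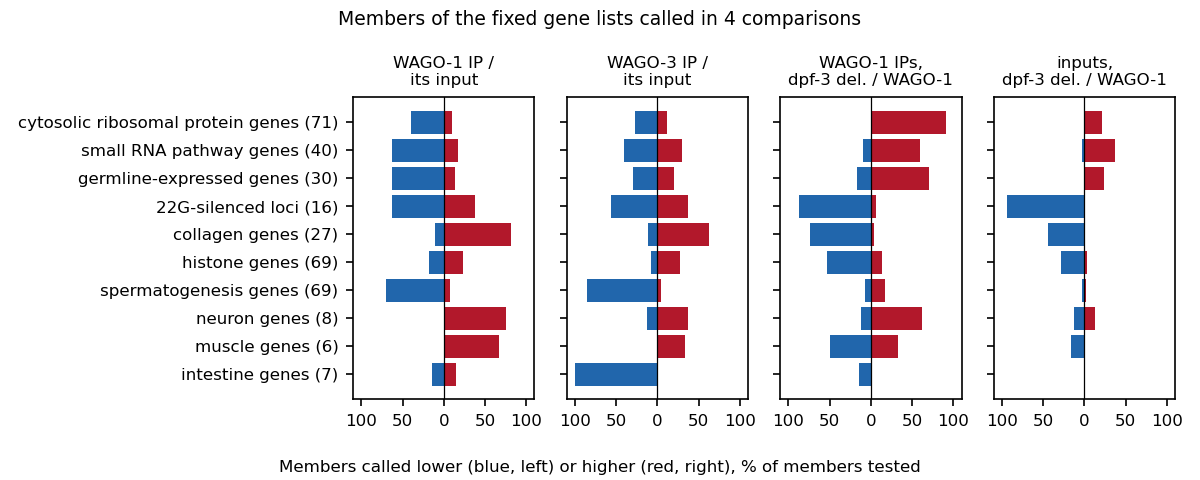
Percent of the tested members of each gene list (number in brackets) called higher (red) or lower (blue) in the WAGO-1 and WAGO-3 IPs against their inputs, between the WAGO-1 IPs and between their inputs, on the TMM scale. In the WAGO-1 IPs 65 of 71 ribosomal protein genes were higher in the dpf-3 deletion and 20 of 27 collagen genes lower; with total counts the numbers were 71 and 17.

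The inputs were compared to see how total small RNAs differ with the dpf-3 deletion. Small RNAs from C38D9.2 fell by 4.12 ± 0.11 (3020 ± 142 to 171 ± 34 CPM, adjusted p = 5.20e-68), and log2 folds were -2.80 ± 0.08 for F15D4.5 and -4.92 ± 0.20 for C18D4.6. The deletion inputs had no read from C16C8.20, from the interval over F23A7.5 on chromosome X, from col-154 or from K08D12.4, which makes them at least 39.2-fold, 35.3-fold, 24.8-fold and 12-fold lower. C16C8.20 was nearly absent from the WAGO-3 inputs too, where dpf-3 is intact (1 read, against 227 in the WAGO-1 inputs). The ribosomal protein gene rpl-39 was higher, at 42 reads in the deletion and 3 in the WAGO-1 inputs (ratio 27.4, exact 95% interval 8.76 to 138). Higher in the deletion input were also gpdh-1, a glycerol-3-phosphate dehydrogenase (2.86 ± 0.55), dcn-1 (3.01 ± 0.64), lsl-1 (2.66 ± 0.37), ppw-2 (1.51 ± 0.12, 197 ± 42 to 579 ± 57.4 CPM), wago-1 (1.47 ± 0.24) and znfx-1, a helicase of germ granules (1.1 ± 0.13).

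By list, 15 of 16 22G-silenced loci were lower in the deletion input and none higher (adjusted p = 6.97e-24, and 0.0036 with an estimated correlation), although with total counts 5 were lower and 6 higher. Small RNA pathway genes were higher for 15 of 40 and lower for 1 (adjusted p = 2.01e-05, and 0.0036 with an estimated correlation), and germline genes higher for 7 of 30 and lower for 0 (adjusted p = 0.001, and 0.0491 with an estimated correlation), among them pgl-1 (1.25 ± 0.15) and klp-7 (1.08 ± 0.13). Ribosomal protein genes were higher for 15 of 71 and lower for none (adjusted p = 4.97e-05, and 0.244 with an estimated correlation), and with total counts for 48 and none. Collagen genes were lower for 12 of 27 (adjusted p = 0.001, and 0.175 with an estimated correlation), with col-157 at 465 reads in the WAGO-1 input and 2 in that of the deletion (exact 95% interval of the ratio 32.7 to 983). Histone genes were lower for 20 of 69 and higher for 2 (adjusted p = 0.0255, and 0.542 with an estimated correlation), with his-61 falling by 5.30 ± 0.39 and his-24 by 2.11 ± 0.09, and the median of that list moved from -0.72 to 0.04 with total counts. In the WAGO-3 input, with dpf-3 intact, his-61 was also lower than in the WAGO-1 input, by 4.75 ± 0.32. There 16 histone genes were lower and 2 higher. Adjusted over the list alone, the higher and lower counts were 0 and 15, 16 and 1, 9 and 0, 14 and 0, 0 and 12, and 2 and 21. Spermatogenesis genes (1 higher and 2 lower of 69, adjusted p = 0.412, with spe-12 at 1.48 ± 0.15), muscle genes (0 and 1 of 6, 0.908), neuron genes (1 and 1 of 8, 0.623) and intestine genes (0 and 0 of 7, 0.675) did not pass, nor did fry call them. With total counts, higher and lower counts were 28 and 0 for small RNA pathway, 25 and 0 for germline, 1 and 9 for collagen, 8 and 14 for histone, 12 and 1 for spermatogenesis, 0 and 0 for muscle and for intestine, and 2 and 1 for neuron genes.

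In total 1007 features were higher and 1734 lower in the deletion input by edgeR's test, and 3413 and 1180 with total counts. Across the 4277 features with a mean of at least 20 CPM in these inputs, log2 folds between the IPs and between the inputs, which share no library, had a Pearson correlation of 0.913 and a Spearman correlation of 0.829. This is a correlation across features, which are not independent replicates. Among all 11648 features tested, 2538 were called in both comparisons and 2526 of them moved in the same direction. Of these, 844 were higher in both, where independent lists would share 308, and 1682 lower in both, against 552. Intervals were called lower more often than genes between the IPs (83.4% against 22.6%) and between the inputs (46.4% against 9.2%). Independent lists are therefore a low baseline here too.

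**Figure D4:**
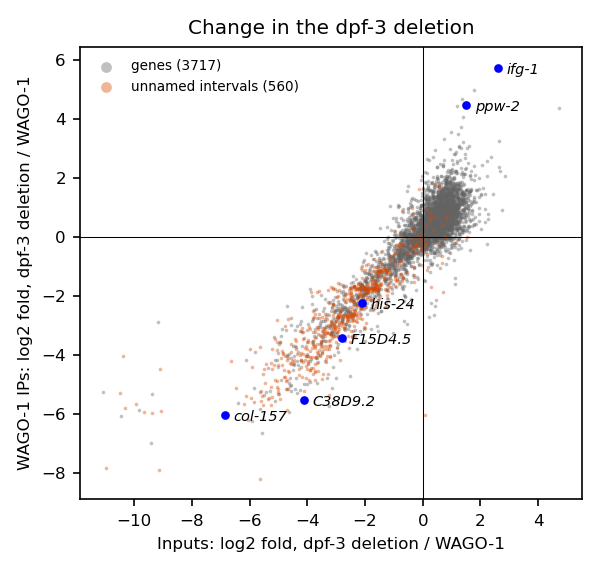
Log2 fold of the dpf-3 deletion over WAGO-1 between inputs (x) and between IPs (y), for 3717 genes and 560 unnamed intervals with a mean of at least 20 normalised CPM in the inputs, on the TMM scale. The folds correlated across features (Pearson 0.913); points far to the left have no read in the deletion inputs, and their fitted fold is not a measured size.

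The change of enrichment asks whether the IP changed beyond its input in the dpf-3 deletion. Enrichment with WAGO-1 rose most clearly for ppw-2, the gene of WAGO-3, by a log2 difference of 2.95 ± 0.16 (adjusted p = 4.13e-34): its small RNAs were below the input with dpf-3 intact (59.1 ± 0.76 CPM in the IP, 197 ± 42 in the input) and above it in the deletion (1308 ± 3.46 and 579 ± 57.4). How far ppw-2 lies above the input rests on the scaling. Per 1e+06 feature counts it stood at 1397 ± 28.8 in the deletion IP and 1303 ± 107 in its input, and the libraries of the 2 groups overlapped. It rose for prp-8 (3.30 ± 0.21), dkc-1 (3.23 ± 0.39), larp-1 (3.19 ± 0.23) and ifg-1 (3.11 ± 0.28). Enrichment fell for an interval at chromosome IV, 16312640 to 16312701, plus strand, over the pseudogene rac-3 (-6.11 ± 0.55), and for ZK250.13 (-4.39 ± 0.81), F56F10.1 (-3.02 ± 0.42), C36E6.2 (-2.76 ± 0.36), T20F5.6 (-2.54 ± 0.31) and uso-1, a vesicle tethering factor (-2.53 ± 0.34). C38D9.2 fell by 1.4 ± 0.16, a call lost with all counted reads as the scaling (-0.35, adjusted p = 0.172).

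Small RNA pathway genes gained enrichment for 7 of 40 and lost it for 1 (adjusted p = 1.16e-06, and 0.0036 with an estimated correlation), among them csr-1 (1.56 ± 0.18), mut-16 (1.85 ± 0.29) and wago-1 (1.21 ± 0.31, adjusted p = 0.0144). The call of wago-1 was lost without replicate B (0.85) or C (1.14) of the WAGO-1 input or replicate C of the deletion input (1.06). A gain can be a smaller depletion: csr-1 had a log2 fold of -2.65 in the WAGO-1 IP and so stayed below the input in the deletion. The median of small RNA pathway genes was below the input in both genotypes (-0.90, and -0.59 in the deletion). Germline genes gained enrichment for 5 of 30 (adjusted p = 0.0011, and 0.0493 with an estimated correlation), pgl-1 by 1.78 ± 0.19 and daz-1 by 2.54 ± 0.36. Of 71 ribosomal protein genes 7 gained enrichment and none lost it, and 22 did adjusted over the list alone (adjusted p = 1.97e-10, and 0.0781 with an estimated correlation), among them rpl-4 (3.09 ± 0.65) and rpl-43 (2.59 ± 0.48). The 22G-silenced loci had 1 higher and 4 lower of 16 (adjusted p = 1.46e-04, and 0.107 with an estimated correlation), and with total counts their direction turned (adjusted p = 0.356). Adjusted over the list alone, higher and lower counts were 9 and 1, 7 and 2, and 1 and 5 for small RNA pathway, germline and 22G-silenced genes. Histone genes (1 and 0 of 69, adjusted p = 0.259), spermatogenesis genes (0 and 0 of 69, 0.908), collagen genes (0 and 1 of 27, 0.541), muscle genes (0 and 0 of 6, 0.684), neuron genes (0 and 0 of 8, 0.986) and intestine genes (0 and 0 of 7, 0.607) did not pass, nor did fry call them. With total counts, higher and lower counts were 12 and 0 for small RNA pathway, 11 and 0 for germline, 22 and 0 for ribosomal, 4 and 2 for 22G-silenced, 4 and 0 for histone and for spermatogenesis, 0 and 1 for collagen and 1 and 0 for muscle genes.

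Enrichment changed for 258 features by edgeR's test, 181 higher and 77 lower. The split was 862 and 44 with total counts. It was 1581 and 36 with replicate A of the WAGO-1 input as the TMM reference, which edgeR also took when replicate A, B or C of the WAGO-1 IP was left out (1618, 1476 and 1524 higher, and 181, 153 and 165 with the reference kept). How many features gained enrichment therefore rests on the scaling. Input depth limits this contrast, since the simulated 2-fold changes were recovered in 17% of cases.

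The last contrast set enrichment with WAGO-3 against enrichment with WAGO-1, to see whether the 2 proteins hold small RNAs of different genes. Enrichment was higher with WAGO-3 for ppw-2, its own gene (log2 difference 2.18 ± 0.17, adjusted p = 4.94e-22), for pgl-1 (2.15 ± 0.20), for csr-1 (1.92 ± 0.18), for znfx-1 (1.58 ± 0.16) and for prg-1 (1.12 ± 0.12), and for fbf-1, a PUF protein of germline stem cells (2.5 ± 0.30). It was also higher for col-157 (1.95 ± 0.16), spe-41 (1.44 ± 0.22) and the 22G-silenced locus C18D4.6 (1.29 ± 0.11). A higher enrichment can be a smaller depletion. The log2 fold of csr-1 in the WAGO-1 IP, -2.65, was larger in size than its difference here, so csr-1 stayed below the input with WAGO-3. The median of small RNA pathway genes was below the input with both proteins (-0.90 with WAGO-1 and -0.29 with WAGO-3). Enrichment was lower with WAGO-3 for R02C2.1 (-6.77 ± 0.70), which stood at 105 ± 8.44 CPM in the WAGO-1 IP and 1.67 ± 1.55 in the WAGO-3 IP, and for rpl-42 (-2.87 ± 0.27), msp-76, a major sperm protein gene (-2.90 ± 0.55), and klp-7 (-1.42 ± 0.17). Y47H10A.5 and K02E2.6 differed by -1.31 ± 0.11 and -1.29 ± 0.12.

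Small RNA pathway genes were more enriched with WAGO-3 for 19 of 40 and less for 6 (adjusted p = 1.56e-05, and 0.0098 with an estimated correlation), and germline genes for 14 and 3 of 30 (adjusted p = 0.001, and 0.0491 with an estimated correlation). Spermatogenesis genes were less enriched for 21 of 69 and more for 3 (adjusted p = 0.0058, and 0.126 with an estimated correlation), and 5 of 7 intestine genes were less enriched (adjusted p = 0.0292, and 0.109 with an estimated correlation), with vha-6 at -3.41 ± 0.77. Adjusted over the list alone, the higher and lower counts were 21 and 7, 14 and 3, 3 and 22, and 0 and 7. The 22G-silenced loci (6 higher and 7 lower of 16, adjusted p = 0.607), histone genes (9 and 2 of 69, 0.276), ribosomal protein genes (7 and 3 of 71, 0.607), collagen genes (3 and 3 of 27, 0.652), muscle genes (0 and 1 of 6, 0.659) and neuron genes (0 and 1 of 8, 0.612) did not pass camera, and fry called muscle genes down (adjusted p = 0.0452). With total counts, higher and lower counts were 17 and 6 for small RNA pathway, 13 and 3 for germline, 3 and 26 for spermatogenesis and 5 and 5 for ribosomal genes. By edgeR's test 1451 features were more enriched with WAGO-3 and 1750 less, 1129 and 2012 with total counts, and 2486 and 1378 with replicate A of the WAGO-1 input as the TMM reference. That reference was also taken without any 1 of the 6 IP libraries, where 2318 to 2503 were more enriched, against 1347 to 1461 with the reference kept.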

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

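The thinned comparison of the WAGO-1 IPs was chosen after the depths were seen, with its prediction written before it was run. The tests of scaling, of input depth for the change of enrichment, of strain, of carried-over RNA and of changes already in the inputs were chosen after the results they bear on were known, and what the splits of libraries would show was also written down after.

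Enrichment differed between groups in a test of the difference itself. In the dpf-3 deletion the enrichment with WAGO-1 changed for 258 features. The log2 differences were 2.95 for ppw-2, 3.30 for prp-8, 3.23 for dkc-1, 3.19 for larp-1, 3.11 for ifg-1, 3.09 for rpl-4, 2.59 for rpl-43, 1.78 for pgl-1, 2.54 for daz-1, 1.56 for csr-1, 1.85 for mut-16 and 1.21 for wago-1. They were -1.40 for C38D9.2, -4.39 for ZK250.13, -3.02 for F56F10.1, -2.76 for C36E6.2, -2.54 for T20F5.6, -2.53 for uso-1 and -6.11 for the interval over rac-3. Enrichment with WAGO-3 differed from that with WAGO-1 for 3201 features. The log2 differences were 2.18 for ppw-2, 1.92 for csr-1, 1.58 for znfx-1, 1.12 for prg-1, 2.15 for pgl-1, 2.5 for fbf-1, 1.29 for C18D4.6, 1.95 for col-157 and 1.44 for spe-41. They were -6.77 for R02C2.1, -2.87 for rpl-42, -3.41 for vha-6, -2.90 for msp-76, -1.42 for klp-7, -1.31 for Y47H10A.5 and -1.29 for K02E2.6.

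Unnamed intervals fell relative to genes in the dpf-3 deletion, in the IP and in the input. The medians below cover the 1779 of 55259 intervals that passed the filter. The sources used here do not say how the intervals were chosen. A choice that favoured libraries with intact dpf-3 was not tested and cannot be told apart from a fall. A scaling moves genes and intervals alike, so by construction it cannot set their medians apart. The gap between the IPs was -2.12 on the TMM scale, -2.11 with total counts and -2.15 with DESeq2. In the IP the third quartile of intervals lay below the first quartile of genes (difference -0.57), which describes their spread and does not test scaling. With IPs thinned to the depth of the inputs, the median of intervals minus that of genes was -2.04 (-2.12 unthinned). Thinning draws reads at random and keeps the expected proportions, so a gap of medians could hardly move. No conclusion on the depth of the IPs is drawn from it. A strain difference other than dpf-3 remains a candidate explanation: between the inputs of the WAGO-3 and WAGO-1 strains, both with dpf-3 intact, the median of intervals minus that of genes was -0.94, and each genotype is 1 strain. An effect of the deletion therefore stays open as a hypothesis, untested beyond this.

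Ribosomal protein genes rose together in the WAGO-1 IP of the deletion, though the list was not past the threshold with an estimated correlation (camera adjusted p = 0.0935). Scaling as the whole explanation is argued against, since it moves all genes alike and the first quartile of the list lay 0.69 above the third quartile of other genes. If unbound RNA carried over into the IP were the cause, features depleted at least 8-fold from the WAGO-3 IP should gain as much enrichment as these genes (median 0.99). The 1352 such features had a median of 0.18 (quartiles -0.42 and 0.80), which argues against a carry-over that follows the WAGO-3 profile. Whether the rise is already complete in the inputs stays open, because the list's gain of enrichment over all features, 0.89, was past the threshold at a preset correlation and not with an estimated one (adjusted p = 0.0781).

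Only 258 features changed enrichment while 7268 differed between the WAGO-1 IPs. Noise from shallow inputs does not by itself shrink a median change of enrichment. Where an input group held no read, however, the fitted fold is not a measured size and can shrink it. Features higher and lower between the IPs had medians 2.55 apart there, 2.27 apart between the inputs and 0.33 apart in the change of enrichment. On these fitted folds, this last was 0.134 of the separation between the IPs at most, over the fit and those without 1 input library. An input group was at 0 for 346 of 1779 intervals and 290 of 9869 genes. With such folds set against the floor, the median between the inputs moved from -2.12 to -1.47 for intervals and from 0.196 to 0.194 for genes. The separation was not recomputed at the floor, so whether depth is the whole cause is not settled. How many small changes the depth hides stays open. A test by the thinned IPs had been written beforehand. Thinning left 1113 features higher and 1473 lower between the WAGO-1 IPs, against 3559 and 3709 unthinned, so depth alone removed many calls there. The thinned test is not used here, since those IPs compare 2 groups, and the change of enrichment rests on 4. Scaling stays open as a candidate explanation, since all counted reads per library gave 3882 features with a changed enrichment, and another TMM reference library 1581 with a gain. A change of the small RNA pool shared by IP and input, through the deletion, also remains possible and was not tested apart from the strain.

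Each comparison has 10 splits of its libraries, too few for a share under 0.05. The real split was the 1 split with as many calls in each. It gave 7932 features for the WAGO-1 IP against input, 6294 in the deletion, 7171 for WAGO-3, 7268 between the WAGO-1 IPs, 2741 between their inputs, 258 for the change of enrichment and 3201 between the enrichments with WAGO-3 and WAGO-1. The highest count of any other split was 0 in every case. Each other split mixes libraries of the groups compared, so a real difference adds to the spread within its groups. Few calls were to be foreseen there, and no conclusion is drawn from the splits.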

How the results depend on the processing

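All counted reads as the scaling, the other TMM reference library, the thinned IPs, the fit without both A libraries and the overlaps under total counts were chosen after seeing the data, the other alternatives before. For the 148 results of named genes and intervals, 2404 refits kept direction and call and 7 lost the call: dpf-3 between the inputs (with total counts, without replicate A of the WAGO-1 input and without replicate C of the deletion input), wago-1 in the change of enrichment (without 3 input libraries) and C38D9.2 there (all counted reads). None of these 148 results reversed, but they hold only results that were called. The fold of dpf-3 between the WAGO-1 IPs, which was not called, is not among them, and its direction turned with total counts. Of the alternative counts of features higher or lower, 191 stayed within 1.5 times and 57 moved. The cause was tested only for the TMM reference library, below.

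Higher and lower counts with total counts per library were 1425 and 5696 for the WAGO-1 IP against input, 1487 and 4320 in the deletion, and 1177 and 6085 for WAGO-3. They were 8081 and 1964 between the WAGO-1 IPs, 862 and 44 for the change of enrichment, and 3413 were higher between the inputs. All counted reads gave 5769 and 1264 for the deletion IP against input, 8357 and 1824 between the IPs, 3862 and 20 for the change of enrichment, and 1546 higher between the inputs. Without the filter, 1636 were lower in the deletion IP, 266 higher between the inputs, and 814 and 21 changed enrichment. With only the libraries compared, 570 were higher between the inputs, 2225 and 31 changed enrichment, and 2468 were more enriched with WAGO-3. Annotated coding genes and pseudogenes alone gave 416 and 999 between the inputs. A 2-fold minimum left 1630 higher between the IPs and 662 between the inputs. Thinned IPs gave 1113 and 1473, and leaving out both A libraries 5565 higher.

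With replicate A of the WAGO-1 input as the TMM reference, 5876 were higher between the IPs, 1581 and 36 changed enrichment and 2486 were more enriched with WAGO-3. edgeR takes this reference by itself when any 1 of the WAGO-1 or WAGO-3 IP libraries is left out, and when both A libraries are. With the reference kept as replicate B of the deletion IP, the median fold moved by at most 0.023 in size and leaving out both A libraries gave 3317 higher. With 1 library left out, the higher count between the WAGO-1 IPs ranged from 3296 to 5745, and without replicate A, B or C of the WAGO-1 IP it was 5745, 5397 and 5456, against 3451, 3141 and 3132 with the reference kept. The higher count between the inputs ranged from 655, without replicate C of the deletion input, to 898. For the change of enrichment the higher count ranged from 105, without replicate B of the WAGO-1 input, to 1618, with 1476 to 1618 without any 1 of the WAGO-1 IPs, and the lower count from 31 to 72. For enrichment with WAGO-3 against WAGO-1 the higher count ranged from 1149 to 2503, with 2318 to 2503 without any 1 of the 6 IP libraries and 1347 to 1461 there with the reference kept.

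At 4-fold, shared enriched features numbered 1154 (WAGO-1 and the deletion), 686 (WAGO-1 and WAGO-3) and 692 (the deletion and WAGO-3). With total counts the shared numbers were 291, 68 and 111 at 2-fold and 37, 5 and 7 at 4-fold, where independent lists would share 4.2, 2.1 and 6.1. With an estimated correlation, 3 lists passed for the WAGO-1 IP, 2 for the deletion IP, 1 for WAGO-3, 3 between the IPs, 3 between the inputs, 2 for the change of enrichment and 2 between the proteins. The 22G-silenced loci turned direction with total counts in the change of enrichment (adjusted p = 0.356). The replicate block gave 3581 higher and 3706 lower between the WAGO-1 IPs, where same-letter libraries correlated, and changed no call of a named gene there. In other comparisons the block brought the small RNA pathway list of the deletion IP (adjusted p = 0.0428) and the ribosomal list of WAGO-3 (0.046) past the threshold. It took the 22G-silenced list between the WAGO-3 and WAGO-1 inputs out of it (0.126) and moved no count by over 1.5 times. MicroRNA scaling was not run, since no microRNA gene had a line in the table. Input depth limits both the input contrast and the change of enrichment.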

Other observations

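The comparison of the inputs of the WAGO-3 and WAGO-1 strains and the test of piRNA genes in intervals were chosen after the data were seen.

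The WAGO-3 and WAGO-1 strains both have dpf-3 intact, and their total small RNAs still differed at single loci. Small RNAs from ckk-1, a calmodulin-dependent kinase kinase, stood at 799 ± 35 CPM in the WAGO-3 input and 24.2 ± 6.24 in the WAGO-1 input (SD, n = 3; log2 fold 5.03 ± 0.16 SE, edgeR adjusted p = 4.44e-58). Those from arl-13, a GTPase of cilia, stood at 474 ± 22.9 and 15.3 ± 7.09, from C30G12.1 at 459 ± 28.0 and 11.0 ± 3.65, and from Y54F10AM.11 at 253 ± 21.4 and 3.41 ± 3.07. C55C3.7 was at least 21-fold higher in the WAGO-3 strain, with no read in the WAGO-1 inputs, and F53G2.2 had a ratio of 97.7 (exact 95% interval 17 to 3920). In the other direction, C16C8.20 had 227 reads in the WAGO-1 and 1 in the WAGO-3 inputs (ratio 158, interval 28.1 to 6260), erp-44.2 a ratio of 102 (17.9 to 4040) and F23B12.4 one of 78.6 (26.7 to 383). The 22G-silenced locus R06C1.4 fell by 4.20 ± 0.16 in the WAGO-3 strain, from 754 ± 26.7 to 42.3 ± 11.5 CPM.

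Among the lists in these inputs, histone genes were lower in the WAGO-3 strain for 16 of 69 and higher for 2 (adjusted p = 0.0057, and 0.39 with an estimated correlation), with his-61 falling by 4.75 ± 0.32. The 22G-silenced loci had 3 higher and 3 lower of 16 (adjusted p = 0.0236, and 0.39 with an estimated correlation). The collagen genes col-71 and col-111 were higher by 2.33 ± 0.11 and 1.95 ± 0.10, and the collagen list as a whole did not pass (3 higher and 2 lower of 27, adjusted p = 0.279). The remaining lists did not pass camera either: germline (3 and 0, 0.279), small RNA pathway (4 and 0, 0.311), ribosomal protein (2 and 0, 0.279), spermatogenesis (1 and 0, 0.314), muscle (0 and 1, 0.631), neuron (1 and 0, 0.631) and intestine genes (1 and 0, 0.291). Of the lists that did not pass camera, fry called germline (adjusted p = 0.0034), small RNA pathway (0.0034), intestine (0.0011), spermatogenesis (0.0432) and collagen genes (0.0356) up. In all 667 features were higher and 933 lower, and 695 and 917 with total counts. Tested as 1 list, the 1779 intervals were lower for 458 and higher for 78 (adjusted p = 2.49e-12, and 5.69e-04 with an estimated correlation).

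Some unnamed intervals depleted from the IPs overlap piRNA genes in the RefSeq table, whose products are carried by the Argonaute PRG-1. A candidate explanation for their depletion is that they hold piRNAs, which neither WAGO-1 nor WAGO-3 would then carry. The 9 intervals among the lowest folds, 5 of which overlap a piRNA gene, were left out of the test because they gave rise to it. Of the remaining 28 intervals with a piRNA gene, 22 were lower and 3 higher in the WAGO-1 IP (median log2 fold -4.65), 22 and 2 in that of the deletion (-4.13) and 23 and 3 in the WAGO-3 IP (-4.92). The 1742 intervals without one had medians of 1.73, 1.80 and 2.33, so that the difference was at least 5.93 log2 units in size in each IP (-5.93 in the deletion). The RefSeq table used gives no strand, so the overlap ignores it, and the hypothesis was tested on the same data in which it was seen.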
